A study of Mus musculus with 55 samples.

How the data were processed

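RNA pools from 55 mouse tissues, 1 pool per tissue per the labels, had been hybridised to expression arrays. The value table of the series was used as deposited, with 39309 transcript models and 55 columns, and 0 columns were left unused. Array type, dyes, background correction, normalization and replicate hybridisations are not given in the sources used here. The deposited values are scores on a log-like scale of unstated base. In all models but 1 exactly 27 of the 55 cells were filled and in that model 26 were, all filled values were above 0 (lowest 0.000001, highest 10.09, median 0.41) and 50.9% of all cells were blank. This pattern was read from the values as values relative to each model's median over the 55 samples with those at or below the median blank, and blank cells were set to 0. It follows that the brightness of a spot, the absolute level of a transcript and how far a value lay below the median cannot be recovered, and that the signal over background of the arrays is unknown. The number of arrays limits the precision.

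The design had been fixed for values on the log2 scale with gene symbols. Quantile normalization was to come first only where array medians differed by over 0.5 on that scale. The medians of the filled values ran from 0.29 (Heart) to 0.70 (Olfactory bulb), within that limit as far as an unknown base allows, and the values were used as they stood. The arrays did differ in spread, so quantile normalization and scaling to the same 90th percentile were run as alternatives, and scaling changed some counts strongly. Identifiers were matched to the RefSeq gene table of assembly GRCm38.p6 without versions, and 2 of 39309 matched a transcript accession and 2 more a synonym. The 57 gene lists fixed in advance had 0 measured members, so list tests and marker lists were not run and no list is described. With so few symbols, the rule for named genes, fixed in advance, named identifiers, 2 each way per class comparison, with the largest difference among those past the threshold whose class tissues all lay above the median of the other tissues. None was named downwards because none passed. The stage comparison, in which none passed, named the 2 largest differences each way with the same sign in all 3 pairs, and the tissue leads named in the text were chosen for a wide margin after their values were seen.

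Classes followed textbook anatomy of the tissue in the title and were fixed before the data were examined, as were the tests. Tissues were the units of each test. Brain contains other sampled regions and Large intestine overlaps Colon, so class members are not fully independent. Each of the 7 classes of at least 3 tissues was compared with all tissues outside it except Cortex, by lmFit and eBayes of limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment over 39309 models and a threshold of 0.05. The stage comparison used 3 pairs with the structure as a block. A model was led by a tissue when its value exceeded that of the next tissue by at least 1. Closest tissues were taken from Pearson correlations over the 5000 models with the largest variance, with Cortex left out as a candidate. Class cohesion was tested by enumerating every set of as many tissues among the 54 other than Cortex. Models restricted to a tissue had a value of at least 3 there and at least 1.5 above all tissues except the recipient. Their value also had to be higher than that in the recipient, by any margin. Pairs with at least 20 such models were examined, which gave 1257 pairs from 27 source tissues. Bootstrap intervals used 1000 resamples of models. Correlations, exact rank-sum tests and enumeration were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba, and plots drawn with matplotlib 3.10.9.

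The class fit was tested on simulated data: values of 39309 models were shuffled between tissues, shifts were added to 200 models, and the table was centred and blanked again. Of 25 models raised by 2 units, 22 were recovered for gastrointestinal tract, 23 for central nervous system and blood-forming and lymphoid tissue, 24 for striated muscle, skeleton and teeth and body surface, and 25 for embryo. Of those lowered, 0 were recovered in any class. More unchanged models were called than the threshold allows, 189 beside 56 raised ones in striated muscle and 42 in central nervous system. Each count is therefore printed beside the mean of 5 shuffled tables, and counts with every class tissue above the median were added. A shuffled table holds no raised models, so the adjustment is stricter there than in the real table. Its calls as a percentage of the real count are not the share of false calls, which may be larger. The rank-sum test, which enumerates the null distribution of midranks with ties, recovered from 151 (striated muscle) to 197 (central nervous system) of 200 models raised by 2 units. Its tables were shuffled but not centred and blanked again after the shift.

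Alternatives fixed in advance were quantile normalization, trend and robust variance estimation, a coefficient for each class and remaining tissue, the exact rank-sum test, leaving out adjoining tissues or each class tissue in turn, a minimum difference of 1, Cortex counted in the nervous system, other margins, Spearman correlation and all models. Alternatives added after seeing the data were arrays scaled to the same 90th percentile, the 24655 models with a value of at least 1 in 3 or more tissues, and calls with every class tissue above the median.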

Results

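Transcript levels in 55 mouse tissue samples, each a pool of RNA from a single tissue, structure or cell preparation, were compared on an array table of 39309 transcript models. The models carried RefSeq identifiers of predicted transcripts (39306 of the mRNA series and 3 of the non-coding series). Each value was relative to the model's own median over the 55 samples, on a log-like scale whose base was not stated, and the cells at or below that median were blank. In all models but 1, 27 of the 55 samples held a value, 50.9% of all cells were blank, and the highest value was 10.09. Blank cells entered every calculation as 0, so a difference shows how far tissues rose above the median and understates how far others fell below it. Because the scale's base is unknown, differences are given in units of the deposited scale and not as fold changes.

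The titles placed 34 samples in 8 anatomical classes. These were central nervous system (n = 7), embryo (n = 5), skeleton and teeth (n = 5), gastrointestinal tract (n = 4), blood-forming and lymphoid tissue (n = 4), body surface (n = 4), striated muscle (n = 3) and placenta (n = 2). The other 21 samples stood alone. The sample labelled Cortex was kept out of the classes, and of the tissues that each class was compared with, because its label names no organ. Every tissue was represented by 1 pool, so no value has an error between repeated pools of a tissue. The spread behind each class fit is that between tissues, pooled over the class and the more numerous tissues outside it. A printed SE of a class difference therefore rests mostly on the tissues outside and does not measure the variation within the class. Arrays differed in spread: the 90th percentile ran from 0.61 in Heart to 1.36 in Olfactory bulb, and the number of models above their median from 16019 in ES to 21901 in Cortex. Only 4 identifiers had a gene symbol in the reference table, so transcripts are named by identifier, and only a few per comparison.

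The whole profiles grouped the tissues largely by anatomy. Of the 34 samples in classes, 29 had their closest relative in the same class when Pearson correlations were taken across the 5000 most variable models. Striatum and Hindbrain (r = 0.866), Digit and Snout (r = 0.85), Colon and Large intestine (r = 0.83) and Femur and Knee (r = 0.77) were the closest pairs within their classes, against a median of -0.031 over all 1485 pairs. Tongue was closest to Tongue surface (r = 0.826) and correlated with Skeletal Muscle at 0.378. Bone Marrow was closest to Knee (r = 0.535), and both Spleen (r = 0.559) and Thymus (r = 0.41) were closest to Bladder. For Spleen this held in 2 of 4 alternative settings, with Bone Marrow or Lymph node of its own class closest in the others, and for Thymus in 3 of 4, with Ovary closest in the other. Among samples outside the classes, Thyroid paired with Trachea (r = 0.821), Trigeminus with Striatum (r = 0.666), Epididymus with Testis (r = 0.507), Adrenal with Liver (r = 0.462, in 3 of the 4 settings), ES with Embryo (r = 0.447), Eye with Cerebellum (r = 0.437) and Ovary with Uterus (r = 0.422). Cortex correlated with Striatum at 0.876, the highest value of any pair, then with Midbrain at 0.823 and Cerebellum at 0.806. These correlations run across transcript models, which are not independent replicates.

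**Figure D1:**
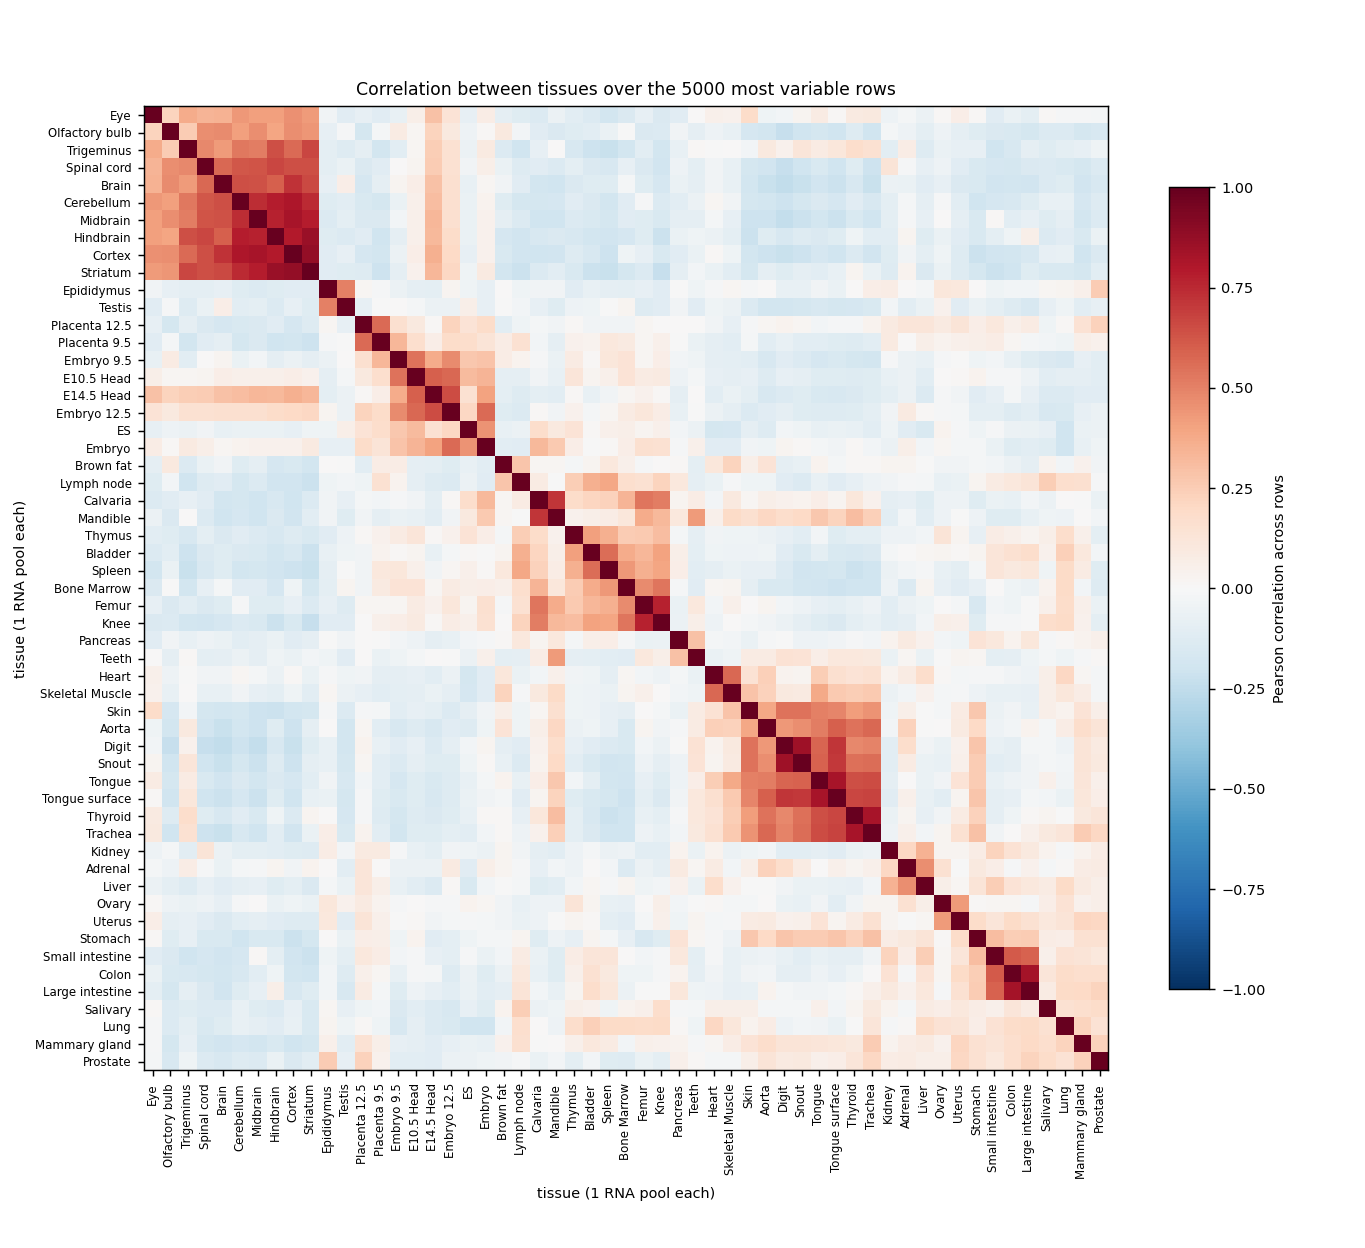
Pearson correlation across the 5000 most variable transcript models between each pair of the 55 samples, ordered by average-linkage clustering, from blue (negative) to red (positive). The block of neural samples at the upper left includes Cortex, which correlates with Striatum at 0.876, and the block of surface samples includes Trachea and Thyroid, which correlate at 0.821.

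On average, tissues of every class resembled each other more than they resembled the tissues outside. Single members could still be closer to an outside tissue: Tongue had a mean correlation of 0.312 with its class and 0.826 with Tongue surface. The mean correlation within the class was 0.642 for body surface (SD 0.138 over 6 pairs), 0.62 for central nervous system (SD 0.137 over 21 pairs), 0.482 for embryo (SD 0.124 over 10 pairs), 0.474 for gastrointestinal tract (SD 0.24 over 6 pairs), 0.398 for striated muscle (SD 0.164 over 3 pairs), 0.388 for skeleton and teeth (SD 0.254 over 10 pairs) and 0.307 for blood-forming and lymphoid tissue (SD 0.1 over 6 pairs). The single pair of placentas correlated at 0.569. The mean correlation with tissues outside the class lay between -0.075 for central nervous system and 0.017 for striated muscle. One-sided exact permutation tests against every set of as many tissues gave Benjamini-Hochberg adjusted p from 9.03e-08 for central nervous system to 0.028 for placenta over the 8 classes. Teeth were the most distant member of any class, with a mean correlation of 0.165 to the other skeletal tissues.

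The central nervous system had a large set of raised transcripts. Set against the 47 tissues outside the class, 2791 transcript models were higher in Brain, Cerebellum, Hindbrain, Midbrain, Olfactory bulb, Spinal cord and Striatum (limma, adjusted p under 0.05), and 1679 of them lay above their median in all 7 tissues. The median difference of these 1679 was 1.21 units, and 368 differed by at least 2 units. The largest differences were those of XM_161929.1, at 5.22 ± 0.36 units (SE, n = 7 against 47, limma adjusted p = 2.15e-17), and XM_161988.1, at 5.16 ± 0.39 units (SE, limma adjusted p = 2.73e-16). XM_161929.1 was lowest in Olfactory bulb at 4.80 and highest in Cerebellum at 6.96, and Eye was the highest tissue outside the class at 3.68. In 65 models every tissue of the class exceeded every tissue outside it except Cortex, where chance ordering would give 0.0. The 1679 models averaged 2.14 units in Cortex, above all 7 class tissues (1.41 to 1.89), then 1.34 in Trigeminus and 1.17 in Eye, against a median of 0.20 over the tissues outside the class. Shuffling each model's values between tissues gave a mean of 8 higher calls, 0.29% of the real count, and asking for a difference of at least 1 left 1129 models. Here and in the other classes this percentage is not the share of false calls, because the adjustment is stricter in a table without raised models.

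Olfactory bulb led the most transcript models within the nervous system, by a margin that shrank when the arrays were scaled. Among the 7 regions, Olfactory bulb led the other regions by at least 1 unit in 1427 transcript models, Brain in 696, Spinal cord in 610, Midbrain in 415, Cerebellum in 383, Hindbrain in 97 and Striatum in 80. Olfactory bulb also had the highest 90th percentile of all arrays. After scaling all arrays to the same 90th percentile, chosen after seeing the data, it led 511 models, Brain 421, Cerebellum 382 and Spinal cord 372. There is 1 pool per region, so these counts have no test.

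Embryonic samples shared many transcripts with moderately raised levels. In E10.5 Head, E14.5 Head, Embryo, Embryo 12.5 and Embryo 9.5, 2948 transcript models were higher than in the 49 other tissues (limma, adjusted p under 0.05), and 1877 of them lay above their median in all 5 samples. The median difference of the 1877 was 0.90 units, and 74 differed by at least 2 units. XM_122474.1 was higher by 3.88 ± 0.47 units (SE, n = 5 against 49, limma adjusted p = 1.49e-08) and XM_122116.1 by 3.68 ± 0.33 units (SE, limma adjusted p = 2.43e-12). XM_122474.1 reached 4.16 in Placenta 12.5, above its 3.85 in Embryo 9.5. XM_122116.1 reached 2.46 in Placenta 9.5, above its 1.96 in Embryo. The 1877 models averaged from 0.65 in Embryo to 1.49 in E10.5 Head, and outside the class they were highest in Placenta 9.5 (0.81) and ES (0.68), which lay above Embryo. Shuffled tables gave a mean of 41 higher calls, 1.39% of the real count. A two-sided exact rank-sum test called 1940 models and a difference of at least 1 left 800.

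Stomach and the intestinal samples shared raised transcripts, most strongly among the intestinal samples. In Colon, Large intestine, Small intestine and Stomach, 1586 transcript models were higher than in the 50 other tissues (limma, adjusted p under 0.05), 1223 of them above their median in all 4 samples, with a median difference of 1.13 units. XM_126148.1 was higher by 6.20 ± 0.50 units (SE, n = 4 against 50, limma adjusted p = 2.36e-14), from 5.47 in Stomach to 7.76 in Colon. XM_133866.1 was higher by 5.69 ± 0.65 units (SE, limma adjusted p = 2.13e-09) and reached 7.16 in Pancreas, close to the 7.21 of Small intestine. The mean of the 1223 models was highest in Colon and lowest in Stomach, at 1.24, and no tissue outside the class exceeded the 0.67 of Liver. In 57 models every gut sample exceeded every other tissue, where chance ordering would give 0.124. Shuffled tables gave a mean of 79.4 higher calls, 5.01% of the real count. An exact rank-sum test called 661 models and a difference of at least 1 left 895.

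Samples of the body surface shared strongly raised transcripts, which were also high in Trachea, Tongue and Thyroid. In Digit, Skin, Snout and Tongue surface, 1211 transcript models were higher than in the 50 other tissues (limma, adjusted p under 0.05), and the 892 that lay above their median in all 4 samples had a median difference of 1.48 units, the largest of the 7 classes. XM_131003.1 was higher by 5.96 ± 0.80 units (SE, n = 4 against 50, limma adjusted p = 1.31e-07) and reached 5.93 in Thyroid, and XM_127192.1 was higher by 5.70 ± 0.89 units (SE, limma adjusted p = 4.43e-06) and reached 7.11 in Tongue. The 892 models averaged 2.40 in Digit and 1.72 in Skin, and outside the class 1.44 in Trachea, 1.40 in Tongue and 1.28 in Thyroid. In 69 models every surface sample exceeded every other tissue, where chance ordering would give 0.124. Shuffled tables gave a mean of 76.6 higher calls, 6.33% of the real count. An exact rank-sum test called 557 models.

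Blood-forming and lymphoid organs had higher transcripts, in a number that some random sets of tissues also reached. None of these transcripts was higher in all 4 organs than in every other tissue. In Bone Marrow, Lymph node, Spleen and Thymus, 1042 transcript models were higher than in the 50 other tissues (limma, adjusted p under 0.05), and 608 lay above their median in all 4 samples, and in 0 models did all 4 exceed every other tissue, where chance ordering would give 0.124. XM_138290.1 was higher by 3.25 ± 0.60 units (SE, n = 4 against 50, limma adjusted p = 0.000443), from 2.33 in Bone Marrow to 6.11 in Spleen, and reached 5.74 in Bladder. XM_129468.1 was higher by 3.05 ± 0.42 units (SE, limma adjusted p = 2.72e-06) and reached 3.13 in Lung. The 608 models averaged 1.82 in Lymph node and 1.19 in Bone Marrow, and outside the class 1.09 in Bladder, 0.98 in Knee and 0.87 in Femur. Shuffled tables gave a mean of 65 higher calls, 6.24% of the real count. Of 100 sets of as many tissues, the class and random others, 5 gave at least 1042 higher models, up to 1904. An exact rank-sum test called only 10 models, a difference of at least 1 left 414, and scaling the arrays to the same 90th percentile left 593. The count was 566 without Lymph node, 653 without Spleen and 2012 without Thymus.

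Skeletal samples shared raised transcripts, though their profiles as a whole differed widely. In Calvaria, Femur, Knee, Mandible and Teeth, 798 transcript models were higher than in the 49 other tissues (limma, adjusted p under 0.05), and 416 lay above their median in all 5 samples, with a median difference of 0.98 units. XM_125226.1 was higher by 4.71 ± 0.62 units (SE, n = 5 against 49, limma adjusted p = 2.68e-07), from 2.71 in Teeth to 7.20 in Femur, and reached 6.86 in Bone Marrow. XM_124596.1 was higher by 4.71 ± 0.62 units (SE, limma adjusted p = 2.67e-07), from 4.09 in Calvaria to 6.61 in Knee, and reached 5.28 in E14.5 Head. The 416 models averaged 1.91 in Femur and 1.28 in Teeth, and outside the class were highest in Bone Marrow at 0.72. Femur correlated with Knee at 0.77 and Calvaria with Mandible at 0.716, while Knee and Teeth correlated at only 0.061. Shuffled tables gave a mean of 30.8 higher calls, 3.86% of the real count. An exact rank-sum test called 134 models, a difference of at least 1 left 316, and the count was 483 without Mandible.

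Muscle samples had higher transcripts that were nearly as high in Tongue surface, in a number that some random sets of tissues also reached. In Heart, Skeletal Muscle and Tongue, 513 transcript models were higher than in the 51 other tissues (limma, adjusted p under 0.05), and 491 of them lay above their median in all 3 samples, with a median difference of 1.07 units. XM_127443.1 was higher by 4.58 ± 0.86 units (SE, n = 3 against 51, limma adjusted p = 0.00065) and XM_125503.1 by 4.08 ± 0.64 units (SE, limma adjusted p = 2.98e-05). In Tongue surface they reached 5.69 and 4.15. The 491 models averaged 1.74 in Skeletal Muscle, 1.48 in Heart and 1.36 in Tongue surface, then 0.99 in Trachea. With Tongue surface left out of the comparison, the models in which all 3 muscle samples exceeded every other tissue rose from 31 to 61, against 1.59 by chance ordering with all tissues. Shuffled tables gave a mean of 166 higher calls, 32.4% of the real count. Of 100 sets of as many tissues, the class and random others, 9 gave at least 513 higher models, up to 1798. A two-sided exact rank-sum test called 0 models, with a smallest p of 4.03e-05, the smallest that an exact test of 3 tissues can give here. After adjustment over all models, a call at that p needs enough models that share it. The 31 models in which all 3 muscle samples exceeded every other tissue have this p and were too few. In a shuffled table the test recovered 151 of 200 models raised by 2 units, but there many models were raised at once. The 0 calls therefore do not show that raised models were absent. The count was 193 without Skeletal Muscle, 278 with a difference of at least 1, 807 with a coefficient for each class and remaining tissue, 1311 after quantile normalization and 1340 with arrays scaled to the same 90th percentile.

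**Figure D2:**
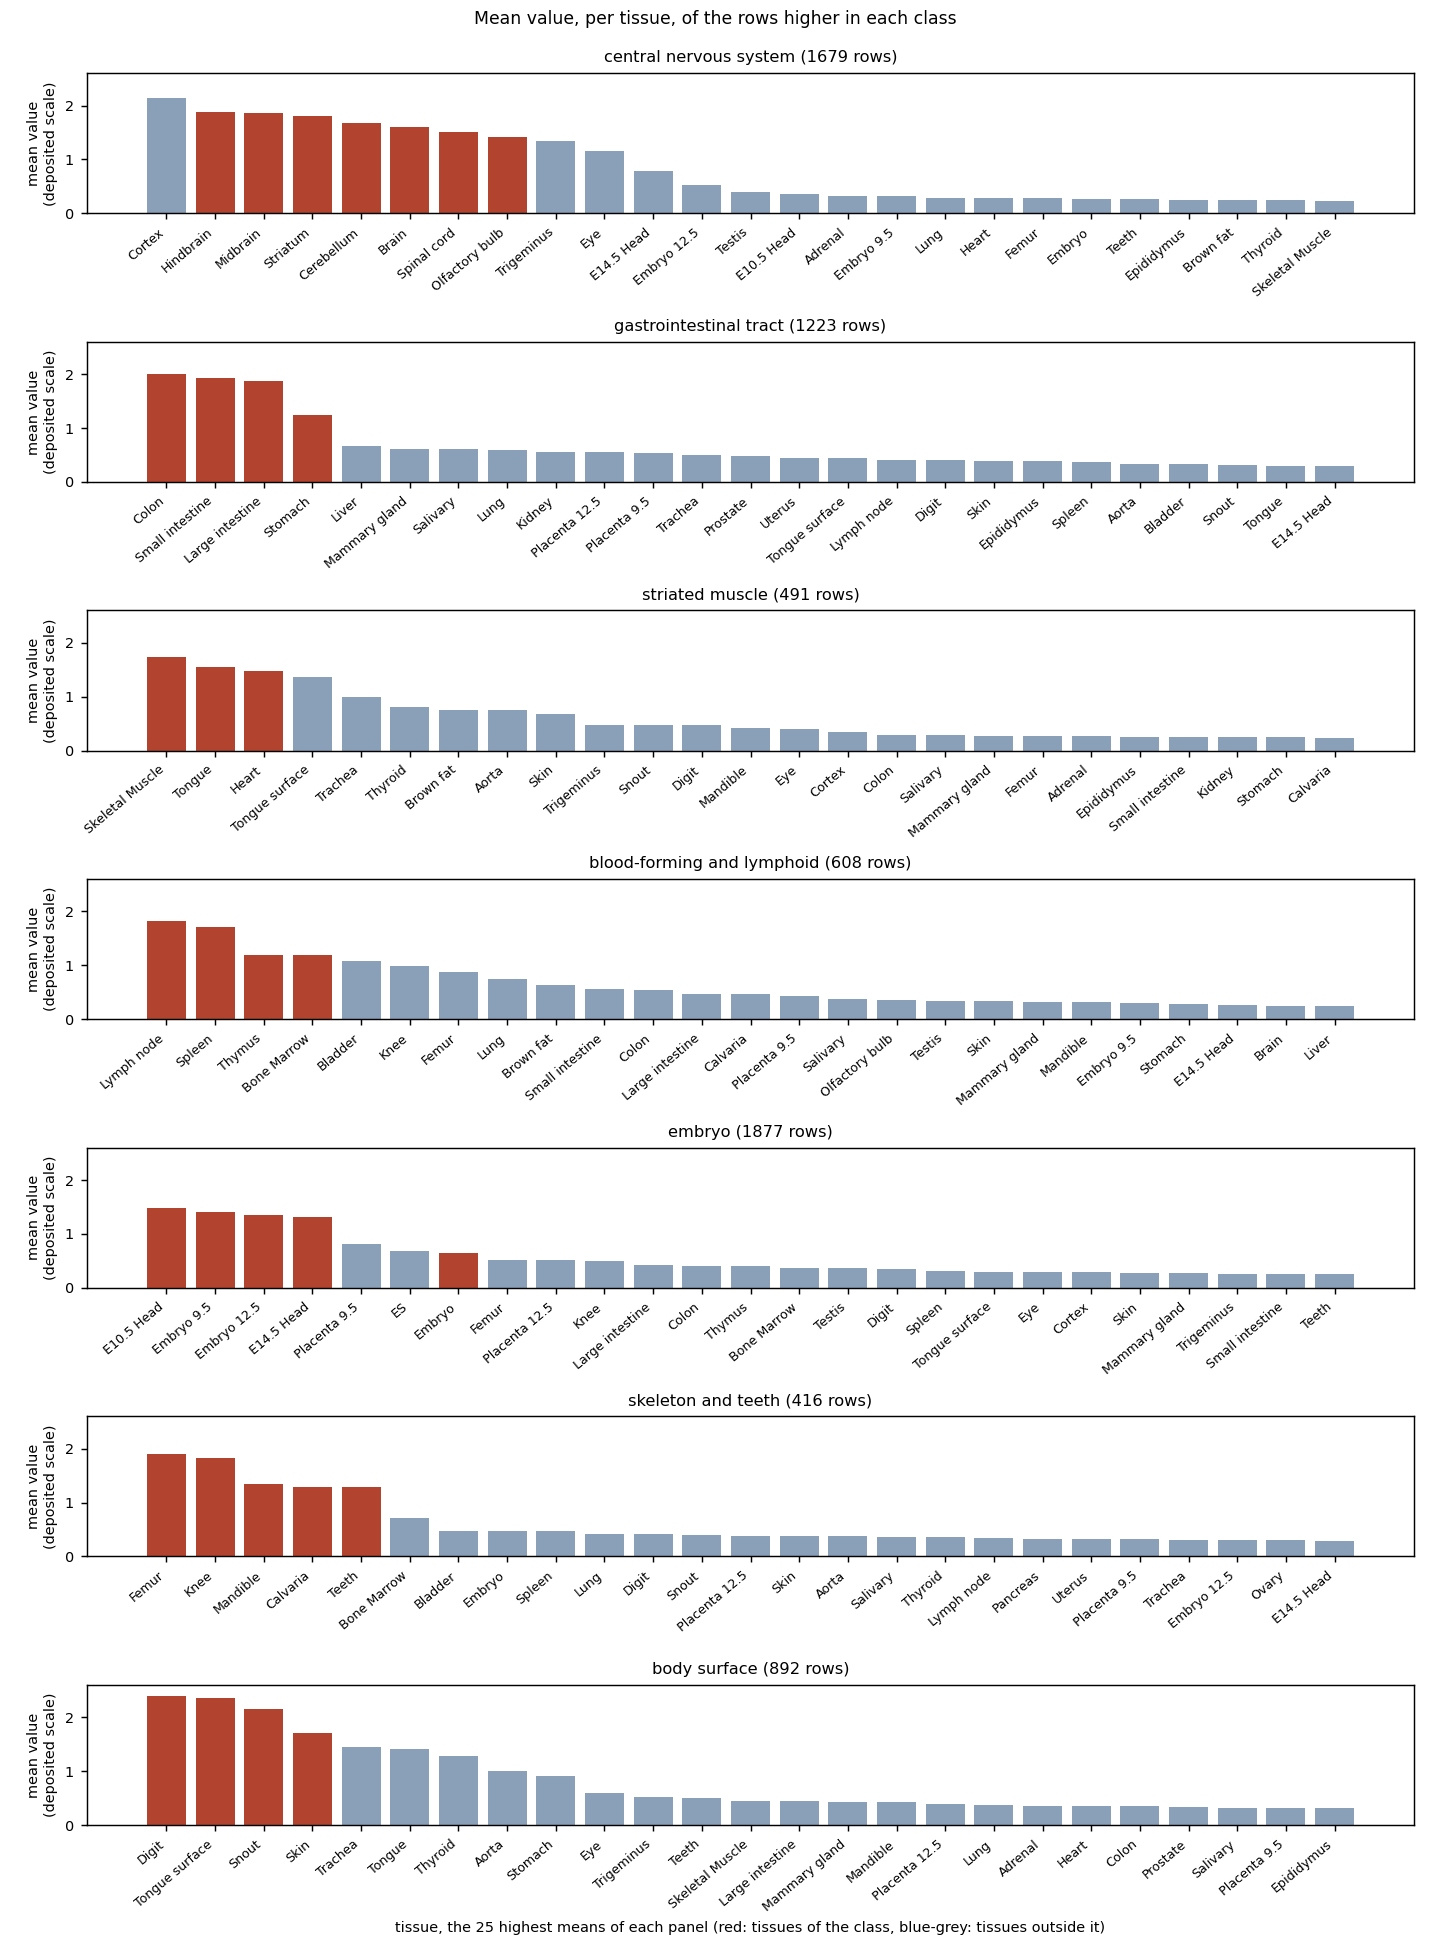
Mean value, in units of the deposited scale, of the transcript models that were higher in each class and above their median in all its tissues, in the 25 samples with the highest means (red: class tissues, blue-grey: tissues outside the class). The models were chosen for being high in the red tissues, so what can be read is the order of the others, led by Cortex at 2.14 for the nervous system, Tongue surface at 1.36 for muscle and Bladder at 1.09 for the lymphoid class.

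No decrease was called in any class by the comparison with all other tissues. No transcript model was lower in any of the 7 classes by limma at an adjusted p under 0.05, with 1894 models at an unadjusted p under 0.05 in the central nervous system, 8 in embryo, 6 in skeleton and teeth and 0 in the other classes. Two-sided exact rank-sum tests called 0 in each class too. At an unadjusted p under 0.05 they gave 4921 lower models in the central nervous system, the most of any class. With the blank cells tied, the smallest exact p of a lower model was 0.0104 in the central nervous system and 0.179 in striated muscle. That left little or no room for a call. In the central nervous system 3410 models (8.67%) lay above their median in none of the 7 tissues, and 2254 in all 7. The count expected by chance was not computed, and the lack of calls does not show that shared decreases were absent. In simulated tables of 39309 models that were blanked below the median in the same way, 0 of 25 models lowered by 4 units were called in each class by that limma fit. A fit with a coefficient for each class and remaining tissue did call lower models, 1713 in the central nervous system and 55 to 569 in the others, and it was not tried on simulated tables.

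Earlier and later stages could be compared in 3 structures, the whole embryo (days 9.5 and 12.5), the head (E10.5 Head and E14.5 Head) and the placenta (days 9.5 and 12.5). No change shared by the structures was detected: 0 transcript models passed an adjusted p of 0.05 in limma with the structure as a block, and 616 higher and 1577 lower models had an unadjusted p under 0.05. In all 3 pairs 1826 models were higher and 4176 lower at the later stage, by at least 1 unit in 10 and 35 of them. The largest differences of 1 sign in all 3 pairs, none of which passed the test, were 2.69 ± 0.16 units for XM_124337.1 (SE, 3 pairs, limma adjusted p = 0.618) and 2.43 ± 0.62 for XM_132236.1. Downwards they were -3.26 ± 0.75 units for XM_137299.1 (SE, 3 pairs) and -3.00 ± 1.21 for XM_139614.1, and limma gave the last 3 of the 4 an adjusted p of 0.668 each. Stage differences correlated weakly between structures across models, at 0.241 for embryo and placenta, 0.153 for embryo and head and -0.004 for head and placenta. The later placenta was lower by at least 2 units in 706 models and higher in 89, the later whole embryo lower in 528 and higher in 89, and the later head lower in 103 and higher in 206. In each structure the stage with more high models had the wider array, with 90th percentiles of 1.20 and 0.75 for Placenta 9.5 and 12.5, 1.15 and 0.87 for Embryo 9.5 and 12.5, and 0.93 and 0.98 for E10.5 Head and E14.5 Head. In simulated tables of 39309 models the fit recovered 0% of models raised by 1 unit, 30.7% of those raised by 4 units and 44% of those raised by 6.

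Testis led more transcripts than any other tissue. It led the next highest tissue by at least 1 unit in 1145 transcript models, 24.3% of the 4712 models led by any tissue, followed by Brown fat (352), Olfactory bulb (320), Salivary (267), Lymph node (212) and Teeth (170). Kidney led 120 models, Small intestine 118, Eye 108 and Liver 106, while Striatum and Embryo led 1 each. XM_155259.1 was led by Salivary with 8.71 against 2.65 in the next tissue, Spinal cord, and XM_136821.1 by Colon with 8.17 against 2.17. Testis kept 571 models at a lead of at least 2 units, Salivary 108, Olfactory bulb 105, Brown fat 100 and Teeth 91. Counts followed the spread of the arrays in part: scaled to the same 90th percentile, an alternative chosen after seeing the data, Testis led 335 models, Teeth 311, Liver 265, Salivary 244, Thymus 163, Brown fat 122 and Olfactory bulb 84. With a lead of at least 2 units 1543 models were led in all, and with 1 pool per tissue no count has a test.

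**Figure D3:**
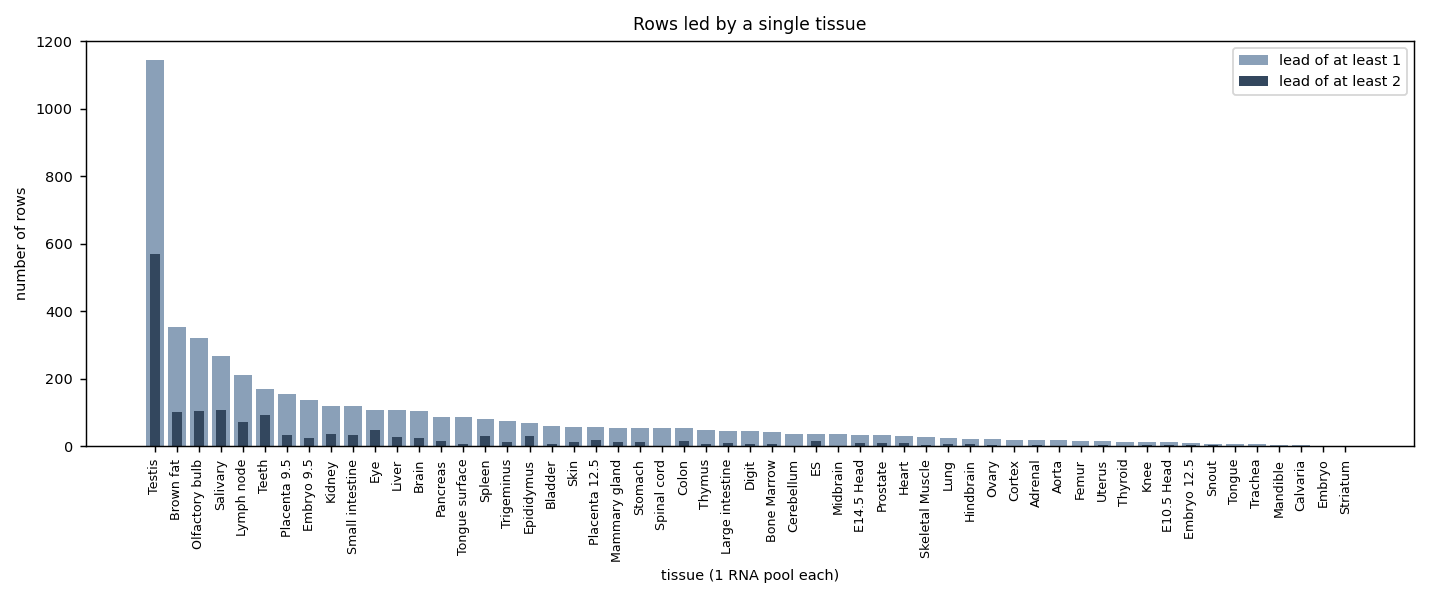
Number of transcript models in which each of the 55 samples exceeds the next highest sample by at least 1 unit (light bars) or at least 2 units (dark bars) of the deposited scale. Testis leads 1145 models, followed by Brown fat with 352 and Olfactory bulb with 320.

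Transcripts restricted to a tissue were also above their median in particular other tissues. Only models higher in the source than in the other tissue were kept, so that the values lay below the source was fixed by this choice. Of 755 models that reached at least 3 units in Testis and exceeded every tissue except Epididymus by at least 1.5, 95.4% lay above their median in Epididymus, at a median of 2.96 units below Testis (quartiles 2.58 and 3.27), and the values correlated across models (r = 0.811). Of 69 models restricted to Liver in the same way, 94.2% were above their median in Adrenal, at a median of 2.43 units below Liver (r = 0.694). Such sets were also seen between tissues that do not adjoin. Of 108 models restricted to Teeth, 90.7% were above their median in Pancreas (r = 0.84). The shares were 86.0% of 50 Small intestine models in Midbrain (r = 0.845), 90.9% of 22 Placenta 12.5 models in Prostate (r = 0.864) and 80% of 65 Eye models in Skin (r = 0.85). Over the 1211 pairs of samples from different classes examined, the median share was 47.7%, and 10 pairs had both r of at least 0.8 and a share of at least 80%. These 10 also held Tongue surface models in Aorta (95.2%, r = 0.834), Trachea (88.0%, r = 0.831), Thyroid (86.4%, r = 0.833) and Tongue (83.3%, r = 0.85), the tissues in which models of the body surface were high, and Pancreas models in Stomach (r = 0.822). These correlations run across transcript models, and the tissue pairs were picked after their values were seen.

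**Figure D4:**
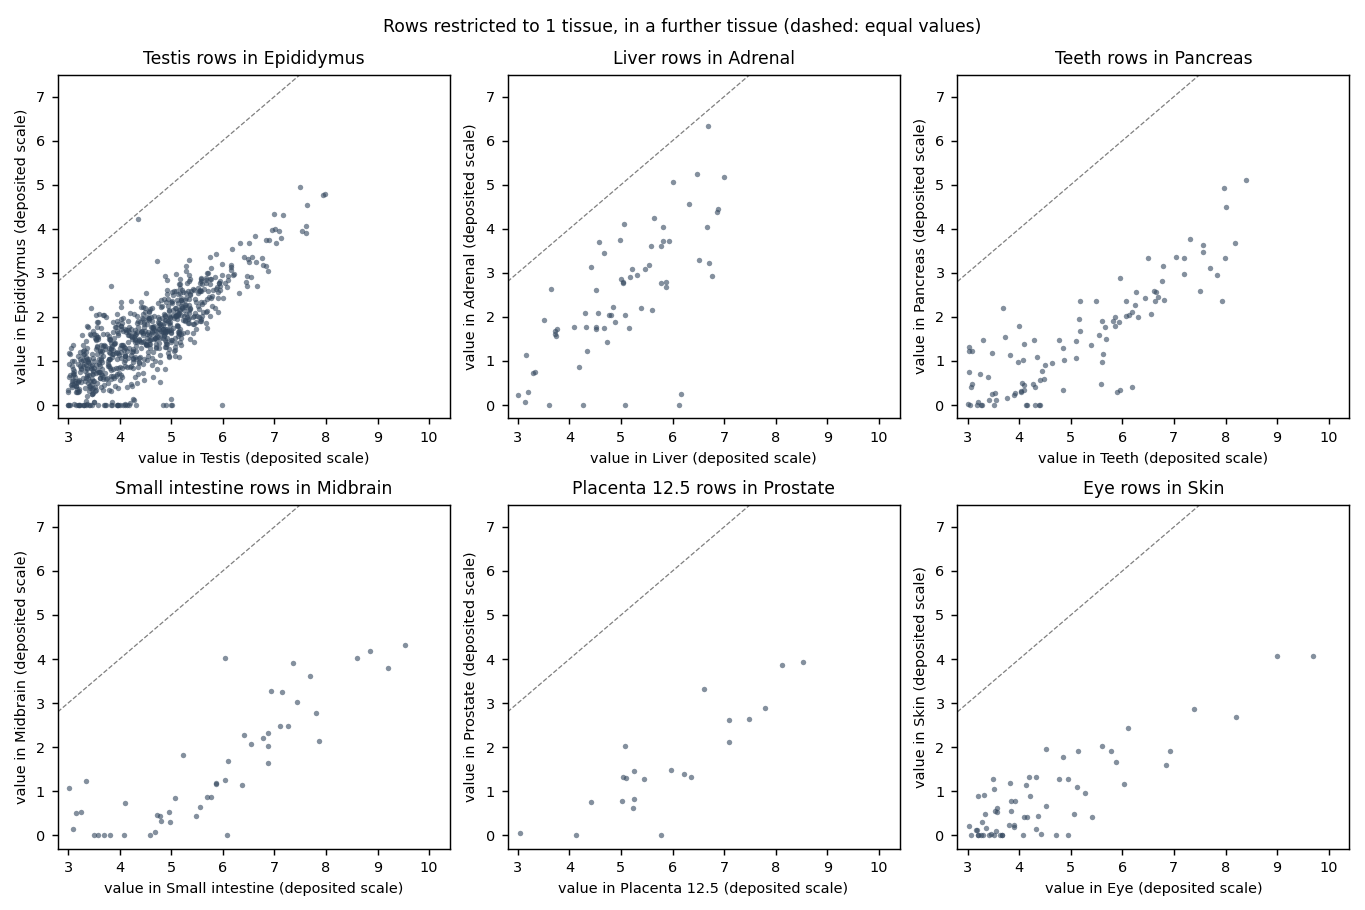
Each point is a transcript model restricted to the tissue on the horizontal axis, with its value in a further tissue on the vertical axis, both in units of the deposited scale, and the dashed line marks equal values. In all 6 panels the points rise together, with r from 0.694 (Liver in Adrenal) to 0.864 (Placenta 12.5 in Prostate). All points lie below the line because only models higher in the source were kept.

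The 4 transcripts with a gene symbol differed in the tissues where they were highest. Zscan4c, a zinc finger gene known from the cleavage-stage embryo and embryonic stem cells, was highest in ES at 5.09, then in Olfactory bulb at 2.61 and Embryo at 1.07. Zkscan16, a zinc finger gene, was highest in neural samples, with 2.74 in Striatum, 2.51 in Midbrain and 2.38 in Cortex. Cstdc3, a gene of the cystatin family, was highest in Mandible at 2.36, then in Calvaria at 1.77 and Prostate at 1.71. BC034090 had its highest value, 0.83, in Thyroid.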

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

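The tests of explanations and of other groupings in this part were all chosen after the results were seen.

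In 30 checks of 5 measures in 6 classes, 8 found a sample apart from the rest of its class, in 6 samples. Each check used Dixon's ratio, the gap to the nearest sample over the range of the class. Its limits give about 1 in 20 by chance for independent, normally distributed values. Counts of led models need not be so distributed and correlations within a class share pairs, so 8 of 30 is not shown to exceed chance. Olfactory bulb led 320 transcript models, against 103 for the next region, and its mean correlation with the other regions, 0.441, was the lowest in the nervous system. Teeth led 170 models, against 15 for the next skeletal sample, and had a mean correlation of 0.165 with the others. Embryo 9.5 led 136 models, against 34 for the next embryonic sample. Small intestine led 118, against 54 for the next gut sample. With arrays scaled to the same 90th percentile, Small intestine led 37 models, fewer than Large intestine (82), Stomach (44) and Colon (42), while Embryo 9.5 led 59 against 30 for E14.5 Head, Olfactory bulb 84 against 47 for Brain and Teeth 311 against 16 for Femur. Spleen had a higher mean correlation with its class, 0.391, than the other lymphoid organs, and Skin had 20028 models above their median, more than the other surface samples. Cortex, which was counted in the class only in an alternative, lay above the median in 97.6% of the 1679 models higher in the central nervous system, against a median of 35.8% over tissues outside the class.

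Transcripts restricted to Testis were found in Epididymus. Their share above the median was 95.36%, and the values followed those in Testis with a slope of 0.765. The Epididymus array was not raised for any set of models: over those restricted to 21 other sources the median share was 40.91%. Across models r was 0.811 (95% bootstrap interval 0.777 to 0.841). RNA of Testis in the Epididymus pool and expression of the genes by the epididymis itself both stay open, since the pair was picked for its share and r.

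Transcripts restricted to Liver were found in Adrenal in the same way. The share was 94.2% with a slope of 0.931, while models of other sources lay above the median in Adrenal in a median of only 33.33%. Across models r was 0.694 (95% bootstrap interval 0.528 to 0.827). Liver RNA in the Adrenal pool and expression of the genes by the adrenal itself both stay open, since this pair too was picked for its values.

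Transcripts of Teeth in Pancreas, of Small intestine in Midbrain, of Placenta 12.5 in Prostate and of Eye in Skin formed the third pattern, 4 of the 10 pairs past the same limits, among which Tongue surface in Tongue, Trachea, Thyroid and Aorta and Pancreas in Stomach were not weighed. The pairs were picked for a correlation of at least 0.8, so their lowest, 0.84, tests nothing, but the highest of the median correlations of the same sources with their other tissues was 0.112, so brighter transcripts were not simply higher everywhere. The receiving arrays were not generally high either, since models of other sources lay above the median in a median of at most 56.98%. Signal carried from the source sample into the other, by mixing of RNA or between hybridisations, stays open, and no label says which samples shared an array or a batch. In the opposite direction the relation was weaker, with r = 0.443 for 27 Pancreas models in Teeth and 0.006 for 25 Skin models in Eye, and no biological explanation was tested.

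Random sets of as many tissues were fitted in place of each class, 100 sets with the real class among them. For central nervous system (2791 higher models, highest other set 1072) and embryo (2948, highest other 711) 1 of the 100 gave as many, the class itself. That is the lowest share that 100 sets can give. For gastrointestinal tract (1586) 2 of 100 gave as many (highest 2506), for body surface (1211) 2 of 100 (highest 3077), and for skeleton and teeth (798) 3 of 100 (highest 1277). These shares are low but not adjusted over the 7 classes, and another set gave a higher count than each of the last 3 classes. The count therefore does not exclude chance for them. Nor can chance be excluded by it for blood-forming and lymphoid tissue (1042), 5 of 100 (highest 1904, a set that holds Lymph node and Spleen), or striated muscle (513), 9 of 100 (highest 1798). Counting only models above the median in every tissue of the set, 4 of 100 gave as many for each of these classes, and the exact permutation test of their mean correlations gave adjusted p of 0.00737 and 0.00912 over 8 classes. The highest other sets point to structure among the samples: for body surface it was Brain, Brown fat, Spinal cord and Testis, arrays of wide spread, and for striated muscle it was E14.5 Head, Embryo 12.5 and Placenta 9.5. The stage comparison of 6 samples allows only 10 splits, too few for a share under 0.05. The real split gave 0 models and the highest other 5955, but that split parts only the placentas and so tests a single pair, and the other splits that part all 3 pairs gave 0.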

How the results depend on the processing

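The array scaling, the requirement on every class tissue and the restriction to models with a value of at least 1 in 3 tissues were chosen after the results were seen. Of 105 alternative values for results over 0, 79 lay within 1.5 times the main value and 26 did not. Another 97 belong to results of 0, and 90 of them were 0 again, which says little because the class fit called no lowered model in simulated tables and the stage fit few changed ones. The cause of the changes was not tested, except where fewer models or tissues enter by construction. Lower models were called in 0 of the class fits except with a coefficient for each class and remaining tissue, which gave 1713 for central nervous system, 156 for gastrointestinal tract, 55 for striated muscle, 226 for blood-forming and lymphoid, 569 for embryo, 372 for skeleton and teeth and 199 for body surface, and 807 higher models for striated muscle. A difference of at least 1 left 1129 higher models for central nervous system, 895 for gastrointestinal tract, 278 for striated muscle, 414 for blood-forming and lymphoid, 800 for embryo and 316 for skeleton and teeth. The exact rank-sum test called 661 for gastrointestinal tract, 0 for striated muscle, 10 for blood-forming and lymphoid, 1940 for embryo, 134 for skeleton and teeth and 557 for body surface. Requiring every class tissue above the median left 1679 for central nervous system, 608 for blood-forming and lymphoid, 1877 for embryo and 416 for skeleton and teeth. Striated muscle rose from 513 to 1311 with quantile normalization and to 1340 with arrays scaled to the same 90th percentile, which lowered blood-forming and lymphoid to 593. Leaving out each class tissue gave 2513 to 2883 for central nervous system, 1086 to 1729 for gastrointestinal tract, 193 (without Skeletal Muscle) to 469 for striated muscle, 566 (without Lymph node) to 2012 (without Thymus) for blood-forming and lymphoid, with 653 without Spleen, 2172 to 3672 for embryo, 483 (without Mandible) to 1190 for skeleton and teeth and 886 to 1289 for body surface. The stage comparison gave 0 models under every alternative, also without each structure. A lead of at least 2 left 1543 led models in place of 4712. Between 29 and 30 of 34 class samples had their closest relative in the class under every setting, and 34 of the 55 samples kept the same closest relative in all 4 alternatives. Shifting each array to a common median, averaging probes of a gene and the list settings were not run, because array medians were mostly blank and genes were not named, and the filter on dim probes removed 0 of 39309 models and so gave no value. Signal over background is unknown.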

Other observations

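The values in this part were computed after the other results were seen, and the tissue leads were picked for a wide margin. Most models that rose far above their own median did so in few tissues. A transcript at a high level in most tissues lies near its median and cannot be counted here. The counts therefore do not tell in how many tissues transcripts were expressed. Of 14579 models with a value of at least 2 units in any tissue, 6851 (47.0%) reached it in a single tissue, 5986 in 2 to 5 tissues and 1742 in 6 or more. Both placentas exceeded every other tissue in 227 models, where chance ordering of a pair would give 27.5, with Cortex left out of the others, and Mammary gland was the tissue whose removal added most to that count (259 models). With Cortex left out, all 7 central nervous system samples exceeded every other tissue in 65 models, and in 146 with Trigeminus left out as well.

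Single tissues gave other wide leads. XM_159279.1 reached 6.08 in Brown fat and at most 0.60 elsewhere. XM_130494.1 reached 6.84 in Eye against 1.60 in Skin, and XM_123398.1 reached 8.55 in Stomach against 2.81 in E10.5 Head. XM_125259.1 reached 9.21 in Small intestine against 3.80 in Midbrain. Of the 1145 models led by Testis, Epididymus was the next tissue in 330, and of the 170 led by Teeth, Pancreas was the next in 45.

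The order of the identifiers carried some structure. Over 39305 pairs of models with neighbouring accession numbers the mean correlation across tissues was 0.053, against 0.012 in random order, and 134 pairs exceeded 0.8, against 19. The share of models with a value of at least 4 in any tissue was 12.6% in the first of 10 equal parts of the accession order and 3.05% in the last.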
